A study of Drosophila melanogaster with 18 samples.

How the data were processed

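RNA of larval eye-antennal discs was sequenced from 18 libraries, 3 for each of 6 genotypes, and groups and replicate numbers were taken from the sample labels. Per the labels' protocols, cells were sorted, RNA was extracted with Trizol, RNA from sorts on different days was pooled into 3 samples per genotype, and libraries were made with the TruSeq RNA kit. The gate of the sort is not given in the sources used here. Per the submitters' processing notes, the authors used Subread, featureCounts and edgeR with the dm6 genome build, and the deposited values are raw read counts per gene. Tool versions, the annotation, the strand setting and any filter are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart and those of close paralogs are uncertain.

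The deposited table held 17529 genes, of which 17425 were matched by identifier to a symbol and position in the Ensembl annotation of the dm6 assembly, and 104 were not. All columns were matched to a sample. The 37 mitochondrial genes held no counts in any library. Totals ran from 22294940 to 35510575 counts per library. With 3 counts taken as the floor over a group, a gene at 0 counts had an upper limit of 0.0351 CPM in control, 0.0379 in scrib, 0.0356 in fos, 0.0346 in CtBP, 0.0326 in scrib fos and 0.0405 in CtBP scrib. Such floors cover counting error only. No pair of libraries of 1 genotype matched within sampling noise (chi-square per degree of freedom 4.41 or more), so all 18 were kept as separate samples. In every genotype the 2 pairs with replicate 1 lay further apart (26.9 to 136.9) than replicates 2 and 3 (4.41 to 18.7), and replicate 1 had the highest share of Hsp70 counts.

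Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by genotype (10834 kept, 6695 removed), scaled with TMM factors and fitted with glmQLFit (robust) in 1 model over all 18 libraries with a coefficient per genotype (12 residual degrees of freedom, biological coefficient of variation 8.88%). Contrasts were tested 2-sided with glmQLFTest and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The 10 comparisons between genotypes and the interactions of scrib with fos and with CtBP were made. Principal components used log2 CPM with a prior count of 2. The pipeline was tested on 18 libraries simulated from the control means, with the depths and spread of the real libraries (10640 genes). Changes were given to the libraries standing for fos, in genes above 1 CPM in control, so genes of lower level were not covered. It recovered 61 of 67 genes changed 1.5-fold (91.0%), 60 of 67 changed 2-fold (89.6%) and 65 of 66 changed 4-fold (98.5%), and 11 of its 197 calls (5.58%) were false. The minimum share that this test required was lowered after the 89.6% was seen.

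A total of 29 gene lists were fixed before the data were examined, as were the tests, their covariates, the rule for named genes and most of the other settings tried. The lists covered JNK and AP-1 targets, JNK components, Hippo targets and components, JAK/STAT, polarity and adherens junctions, septate junctions, basement membrane, cell cycle, cell death, eye specification, photoreceptor differentiation, antenna, Notch targets and Wingless, Dpp and Hedgehog. They also covered EGFR, ecdysone response, immune effectors, stress and detoxification, glycolysis and markers of blood cells, glia, myoblasts and muscle, fat body, salivary gland, trachea, neuroblasts and brain, germline and sex. Of their genes 382 were matched and 2 were not (mir-ban and Pfkfb), and some genes stand in more than 1 list. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation.

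Named genes were the mutated genes and, among called genes with a group mean of at least 10 CPM and no overlap between the libraries of the compared groups, the 8 largest changes each way with a symbol other than an annotation number or noncoding RNA. To these came the 2 largest each way of any symbol and up to 4 members of each list with the smallest p, and other members were named by value. The no-overlap condition is met by chance in 10% of genes for 3 libraries against 3. For comparisons other than those of the single mutants with control and of the double mutants with scrib, and for the interactions, 4 each way were named, for the interactions without the no-overlap condition.

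Other settings chosen beforehand were DESeq2 size factors in the edgeR test, the DESeq2 1.42.0 Wald test, no filter, and a filter of 5 CPM in 3 libraries. Others were a fit of only the compared groups, a replicate block, leaving out each library in turn and a fold change of at least 2. Fits without ribosomal RNA genes, fits without replicate 1 of every genotype and leave-one-out fits for overlaps were added after the data were seen. DESeq2 gave no adjusted p for 217 genes in the interaction of scrib with CtBP and for 6 in each other comparison. Whether replicate numbers pair libraries was judged from the correlation of same-numbered libraries' deviations from their group means. Only in scrib against control did all 3 pairs exceed 0.1 (0.126, 0.119 and 0.143), and the labels do not say what a number stands for. The higher Hsp70 share and the larger distance of replicate 1 in all 6 genotypes are a sign in the data that its libraries share a condition, which is spread evenly over the genotypes. Overlaps of comparisons that share libraries were set beside 20 simulations and beside the overlap of independent lists. In the simulations all 18 libraries, the shared ones included, were drawn anew from the mean levels of the shared genotype, so no gene changed. Correlations were taken over genes above 5 CPM. Arm shares were compared with Fisher's exact test, 2-sided, with 95% intervals. For fos and CtBP against control this was repeated with the genes of the arm with most calls left out, as its calls lower the share of every other arm.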

Results

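Messenger RNA of eye-antennal imaginal discs of Drosophila melanogaster, the larval epithelia that form the adult eye, antenna and head capsule, was measured by RNA sequencing in larvae of the third instar. The 18 libraries fell into 6 genotypes of 3 libraries each. The labels give these as the control with the FRT82B chromosome, the scrib1 mutant (scrib), the fosKM mutant (fos), the CtBP87De-10 mutant (CtBP), the scrib1 fosKM double mutant (scrib fos) and the CtBP87De-10 scrib1 double mutant (CtBP scrib). All genotypes carried the mutant or control 3R arm over a cell-lethal arm with a flippase driven in the eye, a design in which mitotic recombination leaves discs built mostly of cells homozygous for the tested arm. Total counts per library ran from 22294940 (CtBP scrib replicate 3) to 35510575 (scrib fos replicate 3). The control libraries had 28365398, 26576898 and 27357884 counts, and those of scrib 27209937, 26193206 and 26897785. The totals were 25791225, 31282162 and 25672312 in fos and 30403118, 30950240 and 25154988 in CtBP. The remaining libraries had 29499271 and 26091695 counts in scrib fos and 29006625 and 27216655 in CtBP scrib. Of 17529 genes in the table, 10834 had enough counts to be tested. Per the labels each library was a pool of RNA from sorts on different days, and no source used here says that libraries of 1 genotype came from separate animals or crosses, so the p-values measure only the spread between these samples.

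The series title names the JNK and Hippo pathways, epithelial integrity and tumour initiation, and the genotypes set the loss of a polarity gene (scrib) beside the loss of a JNK effector (fos) and of a transcriptional co-repressor (CtBP). Levels below are CPM, mean ± SD of 3 libraries. For CPM, counts were scaled to the library total over the tested genes multiplied by the library's TMM factor. These factors ran from 0.932 in CtBP scrib replicate 1 to 1.04 in control replicate 2. Fold changes are log2 values from edgeR with adjusted p-values over the 10834 genes. Ribosomal RNA took 2.50% to 9.24% of counts, with the highest share in CtBP replicate 1. The Hsp70 heat shock genes took 0.0054% to 0.744%, and in all 6 genotypes their share was highest in replicate 1. It was 0.744%, 0.602%, 0.303%, 0.465%, 0.537% and 0.172% in replicate 1 of control, scrib, fos, CtBP, scrib fos and CtBP scrib. In the other libraries it was at most 0.0883%, except 0.345% in CtBP replicate 2.

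CtBP (FBgn0020496; 3R, dm6 positions 13011649 to 13026275) fell from 822 ± 14.8 CPM in control to 287 ± 8.05 in CtBP (log2 fold change -1.52, SE 0.04, adjusted p = 7.04e-16). It also fell from 878 ± 0.888 in scrib to 343 ± 15.2 in CtBP scrib (-1.35, adjusted p = 6.84e-15). The gene that encodes Fos is kay (FBgn0001297; 3R, 29765995 to 29794113). Its transcript was not lower in the fos mutant, at 103 ± 10.1 CPM against 109 ± 25.0 in control (-0.08, SE 0.13, adjusted p = 1.00). It rose in scrib to 214 ± 10.7 (0.98, SE 0.13, adjusted p = 2.14e-05) and was lower in scrib fos, at 139 ± 17.2, than in scrib (-0.63, SE 0.13, adjusted p = 0.00159). The transcript of scrib (FBgn0263289; 3R, 26536350 to 26604051) was 411 ± 50.0 CPM in scrib and 473 ± 11.8 in control (-0.20, SE 0.07, adjusted p = 0.0232). That call was lost without control replicate 2 (0.0862), control replicate 3 (0.0573), scrib replicate 2 (0.0855) or scrib replicate 3 (0.176). The level of kay in CtBP, 84.3 ± 2.33 CPM, missed the threshold against control (-0.37, adjusted p = 0.0860) and passed it without control replicate 2 (adjusted p = 0.00132) and with DESeq2 (0.0152). Both the kay and the scrib levels leave open what the fosKM and scrib1 alleles do to the protein, which RNA counts do not measure.

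On the first principal component of log2 CPM, which held 58.0% of the variance, the scrib and CtBP scrib libraries lay on one side and control, fos and CtBP on the other, with scrib fos between. The second component (13.8%) set scrib fos apart. The number of genes past an adjusted p of 0.05 ranged from 108 for fos against control to 6438 for CtBP scrib against control. Which direction held more genes depended on the settings in most comparisons with scrib tissue. With DESeq2 size factors, more genes were lower than higher in scrib against control (2890 and 2845). More were higher than lower in scrib fos against control (2578 and 2564), fos (2638 and 2555), scrib (2225 and 1975) and CtBP scrib (2780 and 2550).

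**Figure D1:**
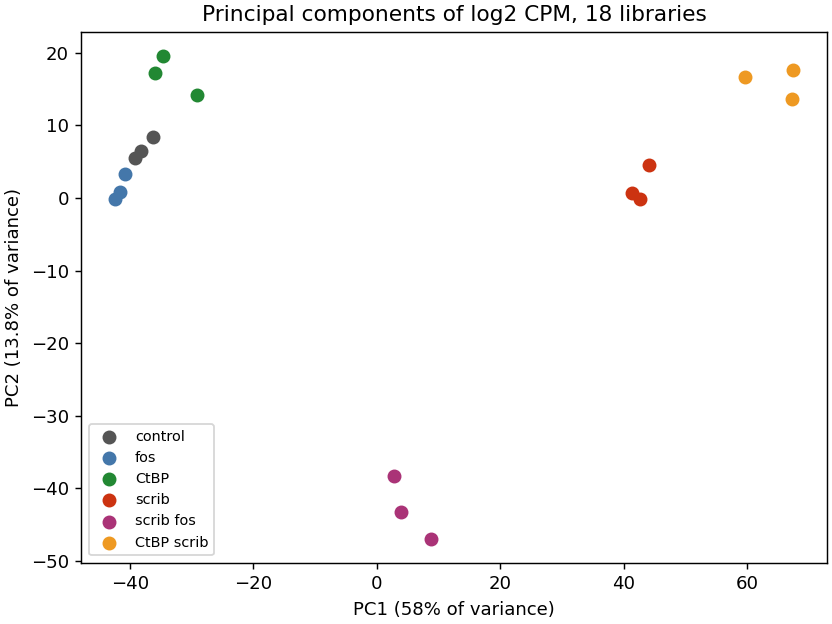
First against second principal component of log2 CPM for the 18 libraries, with the share of variance on each axis and 1 colour per genotype. On the first component scrib lies at 41.3 to 44.1 and CtBP scrib at 59.6 to 67.4, control, fos and CtBP at -42.3 to -29.1, and scrib fos at 2.81 to 8.84 with the lowest second-component values (-46.9 to -38.2).

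**Figure D2:**
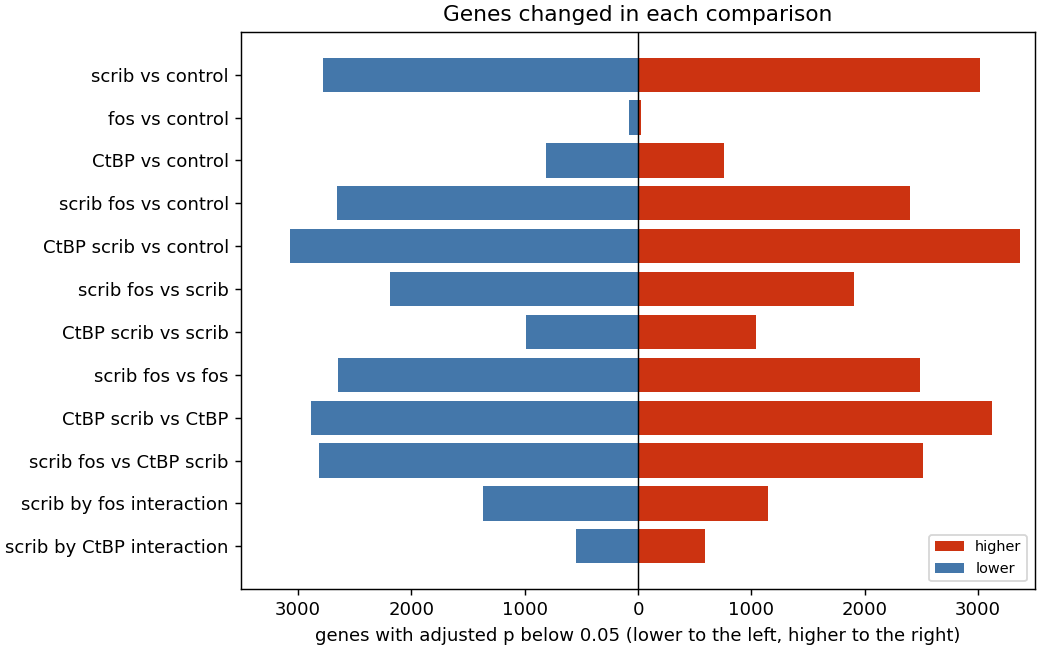
Number of genes with an edgeR adjusted p below 0.05 in each of the 12 comparisons, higher to the right and lower to the left of 0, with 3 libraries per genotype. The bars run from 28 higher and 80 lower genes in fos against control to 3367 higher and 3071 lower in CtBP scrib against control.

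Loss of scrib was compared with control. Targets of the JNK pathway and its transcription factor AP-1 rose: puc, the phosphatase that feeds back on JNK, went from 45.01 ± 4.17 to 124 ± 1.51 CPM (1.46, SE 0.07, adjusted p = 1.10e-12). The matrix metalloproteinase gene Mmp1 went from 54.3 ± 17.9998 to 528 ± 21.4 (3.28, SE 0.20, adjusted p = 9.93e-09). Ilp8, which encodes a relaxin-like peptide that delays metamorphosis, went from 1.71 ± 1.27 to 71.4 ± 10.8 (5.37, SE 0.28, adjusted p = 1.43e-09). The JAK/STAT ligand genes upd1 (3.29, SE 0.16) and upd3 (3.91, SE 0.49) rose as well, upd1 from 3.90 ± 1.47 to 38.4 ± 2.22 CPM. Photoreceptor genes fell, with the receptor tyrosine kinase gene sev at 15.3 ± 1.65 CPM against 277 ± 13.9 (-4.18, SE 0.22, adjusted p = 1.91e-09). The retinal determination gene eya was at 108 ± 8.93 against 357 ± 6.42 (-1.72, SE 0.07, adjusted p = 3.62e-14). In all, 5796 genes changed, 53.5% of those tested, 3014 higher and 2782 lower, and 1520 of them by at least 2-fold, 389 higher and 1131 lower.

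By the fixed rule for named genes, large rises besides those of Ilp8 and upd3 included that of Tektin-C, which encodes a microtubule protein of cilia and flagella (7.27, SE 0.18; 43.9 ± 2.53 against 0.280 ± 0.124 CPM). They also included the tyrosine decarboxylase genes Tdc1 (4.57) and Tdc2 (4.02), aspr (3.78), yellow-b (3.63) and Tig, which encodes the integrin ligand Tiggrin (3.56, SE 0.25; 481 ± 68.3 against 40.8 ± 9.41 CPM). Large falls besides that of sev were those of the cuticle protein gene Cpr97Ea (-4.92, SE 0.14; 1.22 ± 0.221 against 36.9 ± 2.08 CPM) and jeb (-4.07), which encodes the ligand of the Alk receptor. Others were those of the prohormone convertase gene amon (-3.84), fipi (-3.72), Root (-3.71), Rbp6 (-3.54) and the cone cell regulator sv (-3.51). The lncRNA gene CR44024 fell by 4.25 on the log2 scale.

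Of 16 measured JNK and AP-1 targets, 13 rose and 2 fell in scrib (median 1.22, camera adjusted p = 1.11e-06), and the list kept its call with an estimated correlation (adjusted p = 0.0171). The risers included scaf (1.87; 398 ± 28.8 against 109 ± 7.39 CPM), the filamin gene cher (2.09), the PDGF- and VEGF-related ligand gene Pvf1 (2.42), Ets21C (1.91), Atf3 (0.81) and the cell death gene rpr (0.66). The fallers were Ance (-0.76) and Swim (-0.56), and Gadd45 was not called (0.23, adjusted p = 0.328). JAK/STAT genes rose, 7 of 10 (median 0.79, adjusted p = 0.00123), among them the feedback inhibitor Socs36E (1.07; 222 ± 4.69 against 106 ± 8.41 CPM) and chinmo (1.63), with an adjusted p = 0.167 with an estimated correlation. Of 13 measured Hippo pathway targets, the genes driven by Yorkie and Scalloped, 9 rose and 3 fell (median 0.31, adjusted p = 0.0180). Their adjusted p = 0.582 with an estimated correlation. Rises were those of fj (1.22; 515 ± 17.7 against 221 ± 6.51 CPM), kibra (1.43), ex (0.77; 857 ± 89.0 against 503 ± 8.15 CPM) and CycE (0.31), whereas Wnt2 (-1.39), E2f1 (-0.23) and wg (-0.15) fell. The caspase inhibitor gene Diap1 differed by less than its error (0.00, SE 0.05, adjusted p = 0.959). The JNK pathway components went both ways: grnd, a receptor of the JNK-activating ligand Eiger, rose (0.65), as did Jra (0.82) and msn (0.50), whereas the ligand gene egr (-1.46), Traf4 (-1.27) and the receptor gene wgn (-0.45) fell.

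All 20 photoreceptor differentiation genes fell in scrib (median -2.13, camera adjusted p = 1.21e-22; adjusted p = 0.0451 with an estimated correlation), among them ro (-2.88), pros (-3.36) and the proneural gene ato (-1.61; 20.1 ± 1.49 against 61.4 ± 2.67 CPM). Further lists fell under the preset correlation only. They were Notch targets with 12 of 14 lower (median -0.97, adjusted p = 8.38e-08; adjusted p = 0.167 with an estimated correlation), led by E(spl)mgamma-HLH (-2.63). The others were neuroblast and brain markers with 9 of 11 lower and insc higher (median -1.62, adjusted p = 2.64e-04; adjusted p = 0.167 with an estimated correlation). Of 13 eye specification genes 8 fell, with dac at -1.27 and so at -0.80, and Optix (0.37) and tsh (0.16) rose (median -0.44, adjusted p = 0.00280; adjusted p = 0.515 with an estimated correlation). Of 11 antennal genes 8 fell and Awh rose (median -0.62, adjusted p = 0.00280; adjusted p = 0.229 with an estimated correlation). Of 10 EGFR pathway genes 6 fell, aos and pnt by 1.43 each on the log2 scale, and vn (1.19) and spi rose (median -0.44, adjusted p = 0.0131; adjusted p = 0.515 with an estimated correlation).

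The remaining lists were not called in scrib against control, with camera adjusted p-values from 0.0633 to 0.951. Of their measured members, 10 of 18 septate junction genes rose and 1 fell, 8 of 15 polarity and adherens junction genes rose and 2 fell. Further, 13 of 24 cell cycle genes rose and 5 fell, and 6 of 13 cell death genes rose and 1 fell. Among 14 basement membrane genes 4 rose and 6 fell, with Timp at 1.35 and Mmp2 at -1.60. Ecdysone response genes went mostly down, with 2 of 16 higher and 10 lower (adjusted p = 0.0633), which passed the threshold without control replicate 3 (0.00719) or scrib replicate 1 (0.0273), and with no filter (0.0144). Hippo components had 4 of 14 higher and 2 lower, Wingless, Dpp and Hedgehog genes 4 of 14 higher and 5 lower, immune effectors 3 of 8 and 2, stress and detoxification genes 5 of 17 and 3, and glycolytic genes 1 of 12 and 5. Markers of other cell types moved in both directions: blood cells 2 of 12 higher and 6 lower, glia 3 of 8 and 4, myoblasts and muscle 1 of 11 and 5, trachea 2 of 7 and 3, fat body 1 of 9 and 1. Salivary gland markers had 2 of 6 lower, sex markers 2 of 5 lower and germline markers 2 of 8 higher. In this comparison the counts were the same when adjusted over the list alone, except 13 lower Notch targets, 11 lower ecdysone genes, 2 lower septate junction genes, 1 lower Hippo component, 1 higher germline marker and no lower fat body marker. The median and mean differed in sign for basement membrane genes (-0.20 and 0.14), immune effectors (-0.12 and 0.13) and sex markers (-0.09 and 0.03). The camera direction was up, against a median below 0, for the JNK component, immune, stress and fat body lists.

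**Figure D3:**
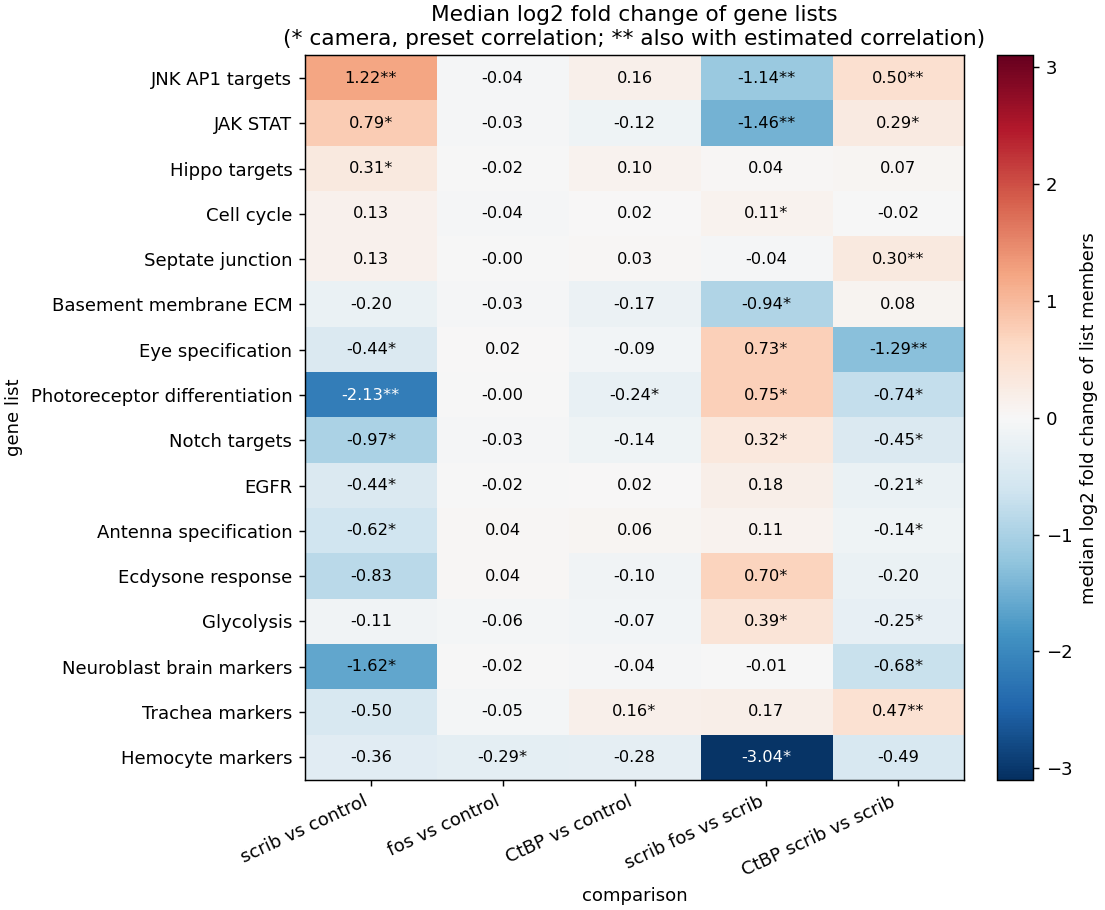
Heat map of the median log2 fold change of the measured members of 16 gene lists (vertical axis) in 5 comparisons (horizontal axis), red for higher and blue for lower, 1 star for a camera call at the preset correlation and a second star where the call also held with an estimated correlation. JNK and AP-1 targets read 1.22 in scrib against control and -1.14 in scrib fos against scrib, and eye specification genes -1.29 in CtBP scrib against scrib.

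Few genes differed between fos and control. The adenylate kinase gene Adk3 rose from 15.1 ± 0.901 to 35.4 ± 0.274 CPM (1.23, SE 0.12, adjusted p = 1.97e-05). Elp2, a subunit of the Elongator complex, rose from 49.7 ± 4.04 to 103 ± 5.55 (1.05, SE 0.06, adjusted p = 1.88e-09). The JNK kinase gene Mkk4 went from 109 ± 1.47 to 152 ± 8.62 (0.48, SE 0.04, adjusted p = 2.01e-06). The photolyase gene phr fell from 77.4 ± 2.43 to 28.7 ± 2.62 CPM (-1.43, SE 0.08, adjusted p = 1.88e-09). The neuronal zinc finger gene nerfin-1 went down from 43.6 ± 2.47 to 27.6 ± 0.824 (-0.66, SE 0.09, adjusted p = 3.23e-04). Of these genes Adk3, Elp2 and phr lie on arm 2R, and in CtBP against control they changed in the same direction (1.257, 0.665 and -1.247). The JNK and AP-1 target list had no member called by edgeR or DESeq2, with 1 higher and 2 lower at an unadjusted p below 0.05. Their leading gene puc was at 39.0 ± 1.59 CPM in fos (-0.21, SE 0.07, adjusted p = 0.284). In all 108 genes changed, 0.997% of those tested, 28 higher and 80 lower. The count was 71 without fos replicate 1 and 57 without fos replicate 2.

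Other named genes of the fos comparison were Ugt36D1 (0.48), the ATF4 gene crc (0.24, SE 0.04; 1306 ± 42.9 against 1108 ± 10.7 CPM), CG14535 (-1.37), the serpin genes Spn47C (-0.89) and Spn55B (-0.60), Fum2 (-0.76) and Prosalpha1R (-0.59), which may share reads with its paralog Prosalpha1. The muscle genes Mlc2 (-0.75, adjusted p = 0.0297) and Act57B (-0.59, adjusted p = 0.0371) and the small rises of Tbcb (0.27), rnh1 (0.26) and MESK2 (0.19) were less firm. The call of Mlc2 ended without control replicate 1 (0.146) or 3 (0.0922) or fos replicate 1 (0.131) or 3 (0.108), and that of Act57B without any of these or control replicate 2 (0.0752 to 0.173). With only the compared groups in the fit, Mlc2 (0.271), Act57B (0.205) and MESK2 (0.0686) were not called, nor with no filter (0.0536, 0.0707 and 0.0615). Without replicate 1 of every genotype none of the 5 was called (0.0578 to 0.368). Tbcb was not called without control replicate 2 (0.0800), fos replicate 1 (0.0566) or fos replicate 2 (0.0695). The call of rnh1 ended without control replicate 2 (0.0669), control replicate 3 (0.0594) or fos replicate 2 (0.130), and that of MESK2 without control replicate 1 (0.190) or 2 (0.0867) or fos replicate 2 (0.136) or 3 (0.190). Of the 108 genes, 49 lay on chromosome arm 2R, 45.4% against 20.04% of the other tested genes (Fisher's exact test, adjusted p = 1.83e-07).

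Among the gene lists only blood cell markers passed camera's test in fos (median -0.29, adjusted p = 0.0272), with an adjusted p = 0.926 with an estimated correlation. No member of that list was called by edgeR or DESeq2, 2 were lower at an unadjusted p below 0.05, and the list was not called without control replicate 3 (0.421) or fos replicate 1 (0.142). Hippo targets had a median of -0.02 (adjusted p = 0.706), with 1 member lower at an unadjusted p below 0.05 and none called by edgeR or DESeq2. ex was at 489 ± 7.41 CPM and Diap1 at 310.0 ± 10.1. Adjusted over the list alone, 2 immune genes, 2 myoblast or muscle genes, 1 stress gene, 1 glial gene and 1 fat body gene were lower in fos, and Mkk4 was the only JNK component called. Uncalled lists that passed with 1 library left out were stress, salivary gland, immune and glycolytic genes without control replicate 2 (0.00178, 0.00178, 0.00643 and 0.0175). Muscle genes passed without control replicate 2 (0.0270) or fos replicate 2 (0.00533). So did cell cycle and ecdysone genes without control replicate 1 (0.0497 each) and fat body genes without fos replicate 1 (0.0112).

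Loss of CtBP was compared with control. The glutathione S-transferase gene GstD3 rose from 0.522 ± 0.262 to 17.2 ± 2.89 CPM (5.01, SE 0.28, adjusted p = 4.93e-09). The serine protease gene ea (3.75) and the cuticle protein genes Cpr92A (3.49) and Cpr49Ah (3.44) also rose. The chromatin remodelling gene Acf went from 42.5 ± 1.68 to 153 ± 7.87 CPM (1.84, SE 0.08, adjusted p = 5.58e-12). CHKov1 fell from 85.8 ± 6.27 to 9.04 ± 0.714 CPM (-3.24, SE 0.08, adjusted p = 1.95e-16), with its neighbour CHKov2 (-2.63), pinta (-3.65), Hsc70-2 (-3.34), Dscam4 (-2.98) and Root (-2.60). The chitin deacetylase genes serp (1.13; 594 ± 56.4 against 271 ± 7.83 CPM) and verm (0.96) and the homeotic regulator tsh (1.12; 256 ± 10.8 against 118 ± 3.91 CPM) rose. JNK target puc did not differ by more than its error (0.01, SE 0.07, adjusted p = 0.959). In all 1566 genes changed, 14.5% of those tested, 758 higher and 808 lower, and 304 by at least 2-fold, 117 higher and 187 lower. Of those 304 genes, 40.5% lay on 3R, the arm that carries CtBP, against 23.6% of the other tested genes.

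Further named rises in CtBP were those of CG6912 (7.12), CG3984 (6.28), Oseg5 (2.32), mey (1.98) and the ecdysone-inducible gene ImpL1 (2.17, SE 0.65, adjusted p = 0.0438), and further falls those of Spn42De (-1.80) and the peptidoglycan receptor gene PGRP-LC (-1.74). The call of ImpL1 ended without control replicate 1 (0.127), control replicate 3 (0.0971), CtBP replicate 1 (0.0584), CtBP replicate 2 (0.134) or CtBP replicate 3 (0.0879). It also ended with only the compared groups (0.181), with no filter (0.0635) and without replicate 1 of every genotype (0.255). GstD genes lie in a cluster of close paralogs, so reads may have been shared among them.

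Among the lists in CtBP, tracheal markers rose (median 0.16, camera adjusted p = 0.00947), with serp, verm and the FGF ligand gene bnl (0.63) higher of 7 measured, and an adjusted p = 0.0880 with an estimated correlation. With only the compared groups in the fit the tracheal list was not called (0.0752). Photoreceptor genes fell (median -0.24, adjusted p = 0.0136; adjusted p = 0.997 with an estimated correlation), with 6 of 20 lower, such as svp (-0.55; 34.2 ± 0.786 against 49.9 ± 1.58 CPM), boss (-0.63) and ato (-0.41), and sca higher (0.44). That call was lost without control replicate 1 (0.0522), CtBP replicate 1 (0.0733) or replicate 1 of every genotype (0.129). As a list, JNK and AP-1 targets were not called (median 0.16, adjusted p = 0.389). Of 16, 4 rose, namely the NADPH oxidase gene Nox (1.04; 45.1 ± 1.21 against 21.9 ± 2.56 CPM), the dual oxidase maturation factor gene mol (1.14), rpr (0.72) and cher (0.30), and Ance and scaf fell (-0.54 each). Hippo targets (median 0.10, adjusted p = 0.230) had 5 of 13 higher, fj (0.39), dally (0.40), kibra (0.35), dlp (0.29) and ex (0.20), and Wnt2 lower (-0.49). Among eye specification genes tsh and tio (0.76) rose and toe (-0.64), eyg (-0.43) and Optix (-0.26) fell (median -0.09, mean 0.01, adjusted p = 0.937). Adjusted over the list alone the counts of higher and lower genes were 1 and 9 for photoreceptor, 6 and 4 for JNK target and 3 and 5 for eye specification genes, and 3 tracheal markers were higher. Blood cell markers (0.00841) and basement membrane genes (0.0421) passed camera's test only without CtBP replicate 3.

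**Figure D4:**
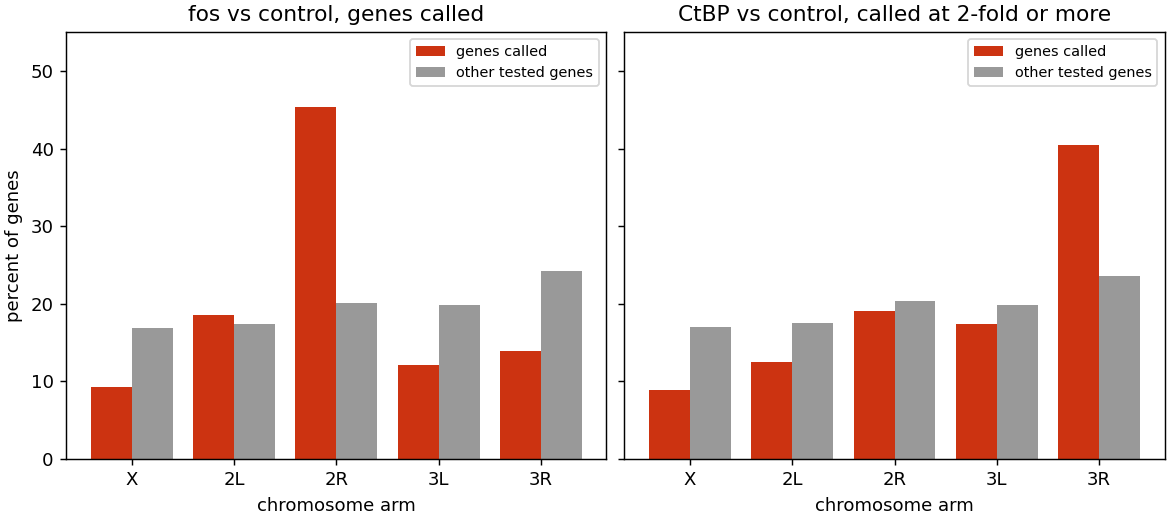
Percent of genes on each chromosome arm (X, 2L, 2R, 3L and 3R on the horizontal axis), called genes in red and other tested genes in grey, for fos against control (all 108 called genes) and CtBP against control (the 304 called at 2-fold or more). Arm 2R holds 45.4% of the fos genes against 20.04% of the others, and arm 3R holds 40.5% of the CtBP genes against 23.6%.

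The scrib fos double mutant was compared with scrib. Genes that had risen in scrib were lower again: puc at 44.9 ± 5.24 against 124 ± 1.51 CPM (-1.46, SE 0.07, adjusted p = 1.92e-12) and Mmp1 at 31.4 ± 5.07 against 528 ± 21.4 (-4.07, SE 0.21, adjusted p = 3.21e-09). Ilp8 was at 1.30 ± 0.203 against 71.4 ± 10.8 (-5.78, SE 0.29, adjusted p = 1.93e-09) and upd3 at 0.577 ± 0.733 against 12.4 ± 1.08 (-4.41, SE 0.52, adjusted p = 1.39e-05). The retinal determination gene eya was higher, at 219 ± 3.21 against 108 ± 8.93 CPM (1.02, SE 0.07, adjusted p = 1.51e-10). The Hippo target Diap1 rose to 457.9 ± 4.07 from 310.3 ± 11.6 CPM (0.56, SE 0.05, adjusted p = 3.21e-08), whereas fj fell to 299.9 ± 7.83 from 515 ± 17.7 (-0.78, SE 0.05, adjusted p = 5.00e-11). In all 4095 genes changed, 1905 higher and 2190 lower, 858 of them by at least 2-fold, 283 higher and 575 lower. More genes were higher than lower with DESeq2 size factors (2225 and 1975), the DESeq2 test (2147 and 1895), no filter (2190 and 1775), a filter of 5 CPM (1950 and 1706) or no ribosomal RNA genes (2285 and 1927).

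Further named falls in scrib fos were CG5399 (-5.84), Tig (-5.57, SE 0.28; 10.1 ± 3.21 against 481 ± 68.3 CPM), yellow-b (-4.30), aspr (-4.26), Tdc1 (-4.22) and the sphingosine kinase gene Sk1 (-3.88). Named rises were the lens protein gene retinin (4.09, SE 0.21; 13.0 ± 0.469 against 0.760 ± 0.127 CPM), Cpr97Ea (3.63), the potassium channel gene SK (2.63) and Spn43Aa (2.32; 272 ± 49.3 against 54.6 ± 7.78 CPM). PGRP-LC (2.23) rose too, as did the ecdysone-induced nuclear receptor gene Hr3 (2.16, SE 0.61, adjusted p = 0.0138), whose call ended without scrib replicate 3 (0.0548) or replicate 1 of every genotype (0.0738). TwdlE (2.26) and lectin-28C (2.00) also rose, and as they overlap on 2L and the strand setting of the counting is not given in the sources used here, their reads could not be told apart.

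Of 16 JNK and AP-1 targets, 13 were lower in scrib fos than in scrib and 2 higher (median -1.14, camera adjusted p = 3.15e-09; adjusted p = 0.00295 with an estimated correlation). Lower members included Pvf1 (-2.14; 14.4 ± 1.49 against 63.6 ± 3.81 CPM), Ets21C (-3.88), cher (-1.60), Atf3 (-0.97) and scaf (-0.87), and rpr lay at the threshold (-0.24, adjusted p = 0.0497). Swim (0.33) and Gadd45 (0.53) were higher and Ance was not called (-0.02, adjusted p = 0.855). Of 10 JAK/STAT genes 8 fell (median -1.46, adjusted p = 3.07e-06; adjusted p = 0.0339 with an estimated correlation), with Socs36E at 75.4 ± 4.83 against 222 ± 4.69 CPM (-1.56), upd1 at -3.66 and chinmo at -2.24. JNK components moved both ways, msn (-0.68) and Jra (-0.54) down and wgn (0.62), Traf4 (0.55) and egr (0.36) up (median -0.04, adjusted p = 0.538). Hippo targets were not called as a list (median 0.04, adjusted p = 0.651). Of 13, 6 rose, namely Diap1, CycE (0.37; 120.2 ± 4.27 against 93.2 ± 6.25 CPM), Wnt2 (0.58), ex, E2f1 and wg (0.19 each), and fj, Myc (-0.60) and dally (-0.16) fell.

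Markers of blood cells fell together in scrib fos against scrib, 11 of 12 (median -3.04, adjusted p = 6.44e-12), with an adjusted p = 0.0657 with an estimated correlation. NimC1 (-3.85; 0.690 ± 0.162 against 9.91 ± 2.11 CPM), Hml (-3.21; 2.71 ± 0.0257 against 25.1 ± 4.05 CPM) and the crystal cell gene PPO1 (-2.90) were among them. The phagocytic receptor gene crq was not called (-0.16, adjusted p = 0.0628). PPO1 and PPO2 are paralogs and may share reads. Basement membrane genes fell with them, 8 of 14 with Mmp2 higher (median -0.94, adjusted p = 3.60e-04; adjusted p = 0.361 with an estimated correlation). The collagen IV genes Col4a1 (-1.98; 12.8 ± 2.12 against 50.7 ± 3.90 CPM) and vkg (-1.85), and Pxn (-2.42), which stands in both lists, were among them. The fall of Tig (-5.57) came together with that of these markers. In scrib against control, however, Tig had risen, whereas both lists had more members lower than higher.

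Eye specification genes rose in scrib fos against scrib, 11 of 13 (median 0.73, adjusted p = 7.07e-11; adjusted p = 0.0657 with an estimated correlation), with dac at 314 ± 12.01 against 141 ± 17.3 CPM (1.15) and dan at 1.25. Photoreceptor genes rose in 17 of 20 cases (median 0.75, adjusted p = 7.77e-11; adjusted p = 0.173 with an estimated correlation), ato by 1.10, ro by 1.39 and sev by 0.99, the last of which stood at 30.5 ± 3.51 CPM against 277 ± 13.9 in control. Of 14 Notch targets 8 rose and E(spl)m3-HLH fell (median 0.32, adjusted p = 0.00468; adjusted p = 0.553 with an estimated correlation), led by E(spl)mgamma-HLH (1.18). Of 12 glycolytic genes 10 rose and Hex-A fell (median 0.39, adjusted p = 1.55e-04; adjusted p = 0.435 with an estimated correlation), with Tpi at 0.74 and Pgi at 0.40. Cell cycle genes rose in 7 of 24 cases, among them CycE, the cyclin gene CycB (0.16) and the mitotic kinase gene aurA (0.24) (median 0.11, adjusted p = 0.0354; adjusted p = 0.697 with an estimated correlation). Ecdysone response genes rose in 7 of 16 with 3 lower (median 0.70, adjusted p = 0.0260; adjusted p = 0.669 with an estimated correlation). The cell cycle call was kept in 7 of 13 alternatives. It ended with only the compared groups in the fit (0.167), with a filter of 5 CPM (0.0545), and without replicate 1 of every genotype (0.0685), scrib fos replicate 1 (0.0637) or scrib replicate 2 (0.0522). The ecdysone call ended with a filter of 5 CPM (0.0545) and without scrib replicate 3 (0.1001). Adjusted over the list alone, the counts for called lists were the same except 9 lower JAK/STAT genes, 12 higher eye specification genes, 9 higher ecdysone genes and 12 lower blood cell markers.

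The CtBP scrib double mutant was compared with scrib. JNK and AP-1 targets were higher still, with puc at 189 ± 3.99 against 124 ± 1.51 CPM (0.61, SE 0.07, adjusted p = 1.02e-06) and Pvf1 at 121 ± 8.73 against 63.6 ± 3.81 (0.93, SE 0.09, adjusted p = 7.49e-07). Mmp1 was at 798 ± 65.7 against 528 ± 21.4 (0.60, SE 0.18, adjusted p = 0.0379). Retinal determination genes fell further, with eya at 52.8 ± 6.02 against 108 ± 8.93 CPM (-1.04, SE 0.07, adjusted p = 5.70e-10) and Optix at 45.5 ± 3.88 against 112 ± 9.59 (-1.29, SE 0.07, adjusted p = 2.08e-11). Septate junction genes rose, such as cora, which encodes the cytoskeletal linker Coracle, from 601 ± 50.2 to 834 ± 32.1 CPM (0.47, SE 0.06, adjusted p = 1.27e-05). In all 2027 genes changed, 1037 higher and 990 lower, 413 of them by at least 2-fold, 139 higher and 274 lower. More genes were lower than higher with no filter (970 and 875), a filter of 5 CPM (942 and 886) or no ribosomal RNA genes (1009 and 997).

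Named rises in CtBP scrib against scrib were CG6912 and CG3984 (6.28 each), GstD3 (4.92, SE 0.21; 72.9 ± 1.26 against 2.40 ± 0.709 CPM), ea (4.55) and thw (3.11; 175 ± 19.8 against 20.3 ± 0.645 CPM). Also higher were eg (2.29), the glucose dehydrogenase gene Gld (2.18), Tdc1 (1.69; 224 ± 1.09 against 69.3 ± 6.33 CPM), Idgf6 (1.66) and IP3K2 (1.58). Named falls were CG31157 (-3.07), Hsc70-2 (-3.05), the tubulin gene betaTub97EF (-2.84), ana (-2.33), ltl (-2.27), Spn43Aa (-2.08), the Pax genes toe (-2.07; 7.44 ± 0.627 against 31.2 ± 4.89 CPM) and eyg (-1.81), and Mrp4 (-1.88).

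Of 16 JNK and AP-1 targets 9 rose and scaf fell (-0.57) in CtBP scrib against scrib (median 0.50, camera adjusted p = 2.66e-05; adjusted p = 0.0210 with an estimated correlation). Atf3 (0.68) and rpr (0.71) were among the risers, whereas Ilp8 (0.04, adjusted p = 0.932) and Ets21C (0.07, adjusted p = 0.932) were not called. Of 10 JAK/STAT genes 5 rose, such as Socs36E (0.62; 341 ± 14.3 against 222 ± 4.69 CPM), upd3 (1.25) and upd1 (0.41) (median 0.29, adjusted p = 0.0198; adjusted p = 0.209 with an estimated correlation). Hippo targets were not called as a list (median 0.07, adjusted p = 0.832), with kibra (0.91; 231 ± 13.4 against 122 ± 11.8 CPM), fj (0.43) and dally (0.17) higher and Wnt2 (-0.71), CycE (-0.33), dlp (-0.22), wg (-0.21) and Diap1 (-0.16) lower. Septate junction genes rose in 15 of 18 cases (median 0.30, adjusted p = 2.00e-08; adjusted p = 0.0350 with an estimated correlation), with sinu at 0.39, cold at 0.32 and vari at 0.29. Tracheal markers rose, 4 of 7, with verm at 1768 ± 39.3 against 777 ± 22.7 CPM (1.19), serp at 1.25 and bnl at 1.31, and dysf fell by 0.80 (median 0.47, adjusted p = 4.39e-05; adjusted p = 0.0186 with an estimated correlation).

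Of 13 eye specification genes 10 fell and tsh rose (0.60) in CtBP scrib against scrib (median -1.29, adjusted p = 2.09e-18; adjusted p = 0.0210 with an estimated correlation), among the falls ey (-1.17), so (-0.95), dan (-1.48) and dac (-1.31). Photoreceptor genes fell in 13 of 20 cases with B-H1 higher (median -0.74, adjusted p = 1.11e-12; adjusted p = 0.117 with an estimated correlation), such as ato (-1.23), boss (-1.89) and sens (-1.62). Antennal genes fell in 5 of 11 cases, al at 10.8 ± 1.09 against 24.4 ± 1.55 CPM (-1.17) and Lim1 (-0.51) among them, and Awh rose (0.81; median -0.14, adjusted p = 0.00334; adjusted p = 0.209 with an estimated correlation). Notch targets were lower in 7 of 14 cases (median -0.45, adjusted p = 2.55e-06; adjusted p = 0.207 with an estimated correlation). EGFR genes were lower in 5 of 10, pnt at -0.74 and vn at -0.61 (median -0.21, adjusted p = 0.00272; adjusted p = 0.260 with an estimated correlation). Glycolytic genes were lower in 8 of 12, led by Hex-A (-0.57; median -0.25, adjusted p = 5.66e-05; adjusted p = 0.260 with an estimated correlation). Neuroblast and brain markers fell in 6 of 11 cases with insc and dpn higher (median -0.68, adjusted p = 0.0129; adjusted p = 0.260 with an estimated correlation). Adjusted over the list alone, the counts for called lists were the same except 16 higher septate junction genes, 14 lower photoreceptor genes, 8 lower Notch targets, 1 higher and 6 lower EGFR genes and 10 lower glycolytic genes. Uncalled lists that passed with 1 library left out were polarity genes (0.00313), Wingless, Dpp and Hedgehog genes (0.00414), JNK components (0.0284), Hippo components (0.0387) and blood cell markers (0.0381) without scrib replicate 1. Without CtBP scrib replicate 3, polarity (0.0427), Wingless, Dpp and Hedgehog (0.0184), sex (0.0427) and blood cell genes (0.0490) passed. Stress genes did so without CtBP scrib replicate 1 (0.0213) and sex markers without CtBP scrib replicate 2 (0.0400) or scrib replicate 3 (0.0427).

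**Figure D5:**
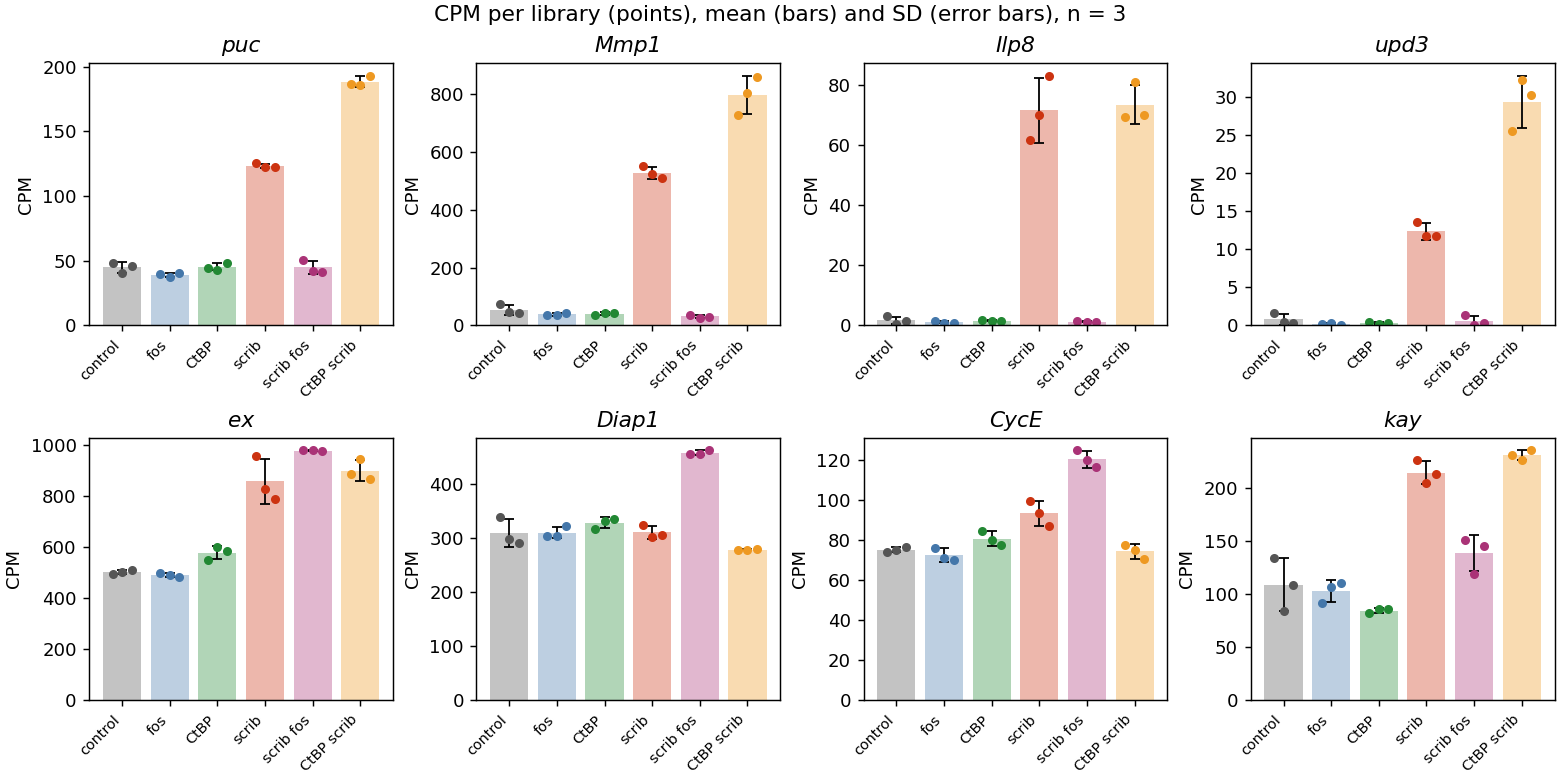
CPM of puc, Mmp1, Ilp8, upd3, ex, Diap1, CycE and kay in the 6 genotypes, 1 panel per gene, with points for the libraries, bars for the mean of 3 and error bars for the SD. The bars of puc read 45.01 in control, 124 in scrib, 44.9 in scrib fos and 189 in CtBP scrib, and those of Diap1 457.9 in scrib fos against 310.3 in scrib.

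Against control, the scrib fos double mutant had higher levels of some Hippo targets: ex was at 977 ± 1.68 against 503 ± 8.15 CPM (0.96, SE 0.06, adjusted p = 1.06e-10) and kibra at 118 ± 5.67 against 45.5 ± 3.01 (1.37). Diap1 was at 457.9 ± 4.07 against 309.5 ± 25.9 (0.57, SE 0.05, adjusted p = 3.06e-08). As a list 8 of 13 rose and 2 fell (median 0.44, adjusted p = 2.43e-04; adjusted p = 0.260 with an estimated correlation). Cell cycle genes rose in 18 of 24 cases, with CycE at 0.68 and CycB at 0.39 (median 0.26, adjusted p = 7.16e-05; adjusted p = 0.393 with an estimated correlation). JNK and AP-1 targets were not called (median 0.00, adjusted p = 0.735), puc being level with control (-0.01, adjusted p = 0.963), scaf higher (1.00) and Mmp1 lower (-0.79, adjusted p = 0.00420). The largest named falls were blood cell genes, PPO2 (-5.15), PPO1 (-5.10), eater (-4.25) and Hml (-4.04), and the largest named rises Tektin-C (7.41), retinin (3.12), dpr16 (2.55) and TwdlE (2.12). Markers of blood cells were lower in 10 of 12 cases (median -3.63, adjusted p = 3.94e-08; adjusted p = 0.137 with an estimated correlation). Glial markers were lower in 6 of 8 (median -1.05, adjusted p = 6.68e-04; adjusted p = 0.112 with an estimated correlation). Myoblast and muscle markers were lower in 7 of 11 (median -1.03, adjusted p = 6.68e-04; adjusted p = 0.137 with an estimated correlation). In all 5054 genes changed, 2398 higher and 2656 lower, and of the 1171 at 2-fold or more 91 were higher and 1080 lower. Against fos alone, 5138 genes changed, 2491 higher and 2647 lower (96 and 1005 at 2-fold or more). Hippo targets stood there at a median of 0.49 and 9 of 13 higher (adjusted p = 1.23e-04; adjusted p = 0.259 with an estimated correlation). JNK targets were not called (median 0.09, adjusted p = 0.504), and pros (-4.06) and lectin-28C (2.52) were among the named genes.

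CtBP scrib against control changed 6438 genes, 3367 higher and 3071 lower, and of the 1898 at 2-fold or more 519 were higher and 1379 lower. JNK and AP-1 targets rose in 13 of 16 cases (median 1.55, adjusted p = 8.48e-08; adjusted p = 0.00937 with an estimated correlation), puc by 2.07 (SE 0.07, adjusted p = 2.30e-15). Septate junction genes rose in 15 of 18 cases (median 0.43, adjusted p = 4.21e-04; adjusted p = 0.160 with an estimated correlation). Hippo targets missed the threshold (median 0.46, adjusted p = 0.0756) and passed it without CtBP scrib replicate 3 (0.0454), while kibra (2.34) and fj (1.65) rose and Diap1 fell (-0.15, adjusted p = 0.0160). Named genes were Tektin-C (7.29), GstD3 (7.10), Tdc1 (6.26), Ilp8 (5.40), ect (-5.30), Rbp6 (-5.08) and jeb (-4.94). The odorant-binding protein gene Obp28a had no counts in CtBP scrib and 11.4 ± 3.099 CPM in control, at least 282-fold lower against a floor of 3 counts over the group. Against CtBP alone, 6014 genes changed, 3127 higher and 2887 lower (510 and 1249 at 2-fold or more), with upd2 (7.94; 40.9 ± 1.44 against 0.165 ± 0.0665 CPM), upd3 (6.59) and Ilp8 (5.47) higher and Osi6 (-5.91), Osi4 (-5.63), superdeath (-4.76) and Rbp6 (-4.69) lower. JNK targets rose there in 12 of 16 cases (median 1.72, adjusted p = 1.16e-06; adjusted p = 0.0208 with an estimated correlation).

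The double mutants were also compared with each other, and 5333 genes differed, 2516 higher and 2817 lower in scrib fos (729 and 731 at 2-fold or more). With DESeq2 size factors 2780 were higher and 2550 lower. JNK and AP-1 targets were lower in scrib fos in 13 of 16 cases (median -1.80, adjusted p = 2.94e-09; adjusted p = 0.00223 with an estimated correlation), puc by a log2 fold change of -2.07 (SE 0.07, adjusted p = 4.60e-15). Eye specification genes were higher in 11 of 13 cases (median 2.05, adjusted p = 2.34e-13; adjusted p = 0.0510 with an estimated correlation), with dac at 314 ± 12.01 against 56.9 ± 10.7 CPM (2.46). CycE (0.70) and Diap1 (0.72) were higher in scrib fos, fj (-1.21) and kibra (-0.97) lower, and ex was not called (0.12, adjusted p = 0.0992). The named genes were betaTub97EF (4.44), Spn43Aa (4.39), ana (3.78) and PGRP-LC (3.55) on the higher side and GstD3 (-7.41), Tdc1 (-5.91), Ilp8 (-5.82) and upd3 (-5.66) on the lower.

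The overlap of the fos and CtBP effects was compared in the 2 backgrounds. Against control, 54 genes changed in the same direction in fos and CtBP, 20 higher and 34 lower, and 4 in opposite directions. Of the 54, 33 lie on arm 2R. Independent lists of these sizes would share 7.93 and 7.69. Unchanged groups, simulated 20 times with all 18 libraries drawn from the mean levels of control, shared none. As they had at most 2 calls in a comparison, that count sets no level for the 54. Across 7900 genes above 5 CPM the correlation of the fold changes was 0.282 (0.493 simulated) and their covariance 0.0128 (0.00747 simulated). Simulated fold changes are noise alone, and the shared group by itself sets their correlation. Simulated correlations, here and below, thus set no level for the real ones, whereas the covariances can be compared. The count was 31 without fos replicate 2. In scrib tissue 313 genes changed the same way in scrib fos and CtBP scrib and 1040 in opposite directions, where independent lists would share 382 and 384, and the covariance was -0.0538 (0.00856 simulated; correlation -0.296 against 0.510). Part of any excess may come from the 3 shared libraries, which are too few to be split into parts of 2, and genes are not independent replicates.

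The overlaps also count the scrib changes that went back, by direction only and not by how far they went. The scrib libraries stand in both comparisons with opposite signs, which by itself favours changes in opposite directions. Of the 5796 genes changed in scrib, 2670 (46.1%) changed in the opposite direction in scrib fos against scrib and 273 in the same, where independent lists would share 1098 and 1092 (correlation -0.680, simulated -0.526; covariance -0.222, simulated -0.00875). In CtBP scrib against scrib, 1123 of them (19.4%) changed further in the same direction and 392 went back, where independent lists would share 543 and 542 (correlation 0.387, simulated -0.511; covariance 0.0921, simulated -0.00841). Here too the simulated correlations come from noise alone and set no level for the real ones. Without shared libraries, the scrib effect was called in the same direction with and without fos for 3366 genes (58.1% of the scrib calls, 249 opposite, correlation 0.708) and with and without CtBP for 4545 (78.4%, 96 opposite, correlation 0.913). Of the 108 genes changed in fos alone, 77 changed the same way in scrib tissue (8 opposite, 21.1 and 19.7 for independent lists). That count was 50 without control replicate 1 and 48, 43 and 51 without fos replicates 1, 2 and 3. Of the 1566 genes changed in CtBP alone, 608 changed the same way in scrib tissue (97 opposite, 146 and 147 for independent lists).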

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

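The tests on attached tissues, chromosome arms, antennal genes and scaling, and the count of balanced regroupings, were chosen only after the results were seen. The second list of blood cell genes was fixed after the marker list was seen to fall but before its own values were looked at, and the other regroupings were set before they were run.

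The effect of losing scrib differed with the state of fos for 2517 genes by the edgeR interaction test, 1145 higher and 1372 lower (1298 and 1234 with DESeq2 size factors). Named differences were those of Ilp8 (-5.06), Tig (-4.50), Tdc1 (-4.13), Tdc2 (-3.99), retinin (3.79), Cpr97Ea (3.63), TwdlE (2.72) and ect (2.54). List medians of this difference were -1.09 for JNK and AP-1 targets (12 of 16 lower, camera adjusted p = 2.80e-11; adjusted p = 0.00131 with an estimated correlation), -1.40 for JAK/STAT (5.49e-07; adjusted p = 0.0225 with an estimated correlation) and -2.62 for blood cell markers (2.96e-13; 0.0460). Medians for lists whose call ended with an estimated correlation were -0.86 for basement membrane (adjusted p = 0.280 with an estimated correlation), 0.70 for eye specification (0.0711), 0.71 for photoreceptor (0.141), 0.26 for Notch (0.613), 0.46 for glycolytic (0.307) and 0.13 for cell cycle genes (0.692). The cell cycle difference was not called without control replicate 3 (0.125) or fos replicate 3 (0.0834).

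The effect of losing scrib differed with the state of CtBP for 1136 genes, 588 higher and 548 lower. Named differences were those of pinta (3.67), CHKov1 (3.12), Dscam4 (2.90), Root (2.60), Cpr92A (-3.53), Cpr49Ah (-2.55), Oseg5 (-2.35) and betaTub97EF (-2.18). Of these, pinta, CHKov1, Dscam4 and Root had fallen in CtBP against control, and Cpr92A, Cpr49Ah and Oseg5 had risen. Except for Cpr49Ah, those changes were close in size to the named differences and opposite in sign. Apart from Cpr49Ah, these genes thus differed little between CtBP scrib and scrib. Calls of this interaction were in excess on arm 3R, so variants carried along with the CtBP mutant arm may account for part of them, as set out below. The eye specification list differed by a median of -1.04 (12 of 13 lower, adjusted p = 2.74e-27; adjusted p = 0.0129 with an estimated correlation). Other called medians were 0.19 for JNK and AP-1 targets (adjusted p = 0.198 with an estimated correlation), 0.43 for JAK/STAT (0.186), 0.22 for septate junction (0.186), -0.50 for photoreceptor (0.261), -0.12 for antennal (0.425), -0.26 for Notch (0.425), -0.18 for EGFR (0.388), -0.14 for glycolytic (0.534), -0.63 for neuroblast (0.261) and -0.57 for sex genes (0.198). The antennal call ended without CtBP replicate 2 (0.0694), CtBP replicate 3 (0.0606), CtBP scrib replicate 3 (0.0672) or scrib replicate 1 (0.0932), with no filter (0.0720), a filter of 5 CPM (0.0724) and only the compared groups (0.134). The sex marker call ended without control replicate 1 (0.0876), control replicate 3 (0.0668), CtBP replicate 1 (0.0710), CtBP replicate 2 (0.0589), scrib replicate 1 (0.0685) or scrib replicate 2 (0.0564), with a filter of 5 CPM (0.0648) and without ribosomal RNA genes (0.0547).

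Regroupings of the same libraries were counted for each comparison. For the interaction of scrib with fos, 2 of 100 regroupings, the real one included, called as many genes (2517 real, 2657 for the highest other). For the interaction of scrib with CtBP, 6 of 100 did (1136 real, 4915 for the highest other). These shares lie under and over the 0.05 set beforehand, but decide on chance for neither interaction. Such counts point to a structure of the samples, as regroupings that place scrib libraries unevenly call many genes. Among the 42 regroupings that placed them evenly for each interaction, the highest counts were 459 and 57, each below the real count. Such regroupings can still mix scrib and other libraries within a group, which raises the spread and lowers the count. They thus do not decide on chance either. Each pairwise comparison has 10 splits, too few for a share under 0.05. In every one only 1 split, the real one, called as many genes. All other splits mix the compared genotypes within a group, which lowers their counts in the same way. The highest other counts were 24 for scrib fos against scrib, 2 for CtBP against control, 1 for fos against control, CtBP scrib against scrib and scrib fos against CtBP scrib, and 0 for the rest, by edgeR.

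Blood cell markers were lower in scrib fos than in scrib, with an adjusted p = 0.0657 for the list with an estimated correlation. A loss of all attached tissue as large as that of the blood cell markers is argued against, as 35 markers of fat body, glia, muscle and trachea had a median of -0.0641 (quartiles -0.61 to 0.65, 10 lower and 4 higher). A smaller loss of glia and muscle stays open, as their lists were lower in scrib fos than in control (medians -1.05 and -1.03). A candidate explanation is that fewer blood cells were among the collected cells: on a second list of blood cell genes 6 of 7 were lower (median -1.32). Their falls were uneven, from Glt at 5.09 against 48.5 CPM (-3.25) to Tep4 at 205 against 245 CPM (-0.25). Tep4 had the highest level of the list and stood at 178 CPM in control. The cells were sorted, by a gate not given in the sources used here, which could have removed blood cells. A change within blood cells, or of these genes in the disc, by genotype was not tested and stays open.

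Genes changed against control were unevenly spread over chromosome arms. For CtBP, genes called at 2-fold or more lay on 3R with an odds ratio of 2.20 (95% interval 1.73 to 2.79), and within 2 Mb of CtBP 30 of 361 genes were called at that size (8.31%) against 4.14% on the rest of 3R, so variants carried along with the mutant arm may account for part of these. Calls of the interaction of scrib with CtBP were in excess on 3R too. Their odds ratio was 1.57 (1.22 to 2.02) at 2-fold or more and 1.22 (1.06 to 1.40) for all calls. In CtBP scrib against scrib it was 1.24 (0.988 to 1.55) at 2-fold or more. Variants on the CtBP arm that the CtBP scrib arm lacks may thus account for part of the interaction calls, which was not tested. For fos the calls were in excess on 2R (odds ratio 3.31, 2.21 to 4.94), and 2L and 2R together had an odds ratio of 2.96 (1.96 to 4.51). The value for 2L was 1.08 (0.627 to 1.77), and 1.84 (1.02 to 3.25) with genes on 2R left out, so the excess on 2L is less firm. On 3R the odds ratio of the fos calls was 0.505 (0.271 to 0.879), but 0.786 (0.405 to 1.44) with genes on 2R left out. The tables thus do not decide whether variants on that arm add to the fos calls. Over all calls, scrib fos had a small excess on 3R against control (odds ratio 1.16, 1.06 to 1.27) and against fos (1.20, 1.10 to 1.32). Against scrib it had none (1.01, 0.921 to 1.11). The cause of this excess was not tested. Of the fos calls on 2R, which include Adk3, Elp2 and phr, 33 of 49 were called the same way in CtBP against control, and 21 of 59 elsewhere (odds ratio 3.68, 1.56 to 9.004, Fisher's exact p = 0.00184), so for these genes an arm 2R of the control stock unlike those of the fos and CtBP stocks is a candidate explanation. The CtBP calls as a whole do not add to it. Their odds ratio was 0.951 (0.828 to 1.089) on 2R and 0.779 (0.694 to 0.874) on 2L and 2R together, or 1.15 (0.996 to 1.33) and 0.968 (0.848 to 1.10) with genes on 3R left out. The CtBP calls on 3L had an odds ratio of 1.21 (1.05 to 1.40) with genes on 3R left out. Adk3 and phr stood near the control level in scrib too, so such a difference could also enter the comparisons of the double mutants with scrib. The calls of those comparisons as a whole were not in excess on 2R. Their odds ratios were 0.966 (0.876 to 1.07) for scrib fos and 0.976 (0.863 to 1.10) for CtBP scrib. The effect of the fos and CtBP genotypes themselves stays open.

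Eye specification genes were lower in CtBP scrib than in scrib. A smaller share of eye cells against antennal cells would raise antennal genes alike. Of 8 antennal genes outside the eye and photoreceptor lists 1 was higher and 4 were lower, and Awh (0.81) and al (-1.17) lay 1.99 apart (SE 0.123), which argues against such a share as the whole cause. With DESeq2 size factors the list median was -1.30. These factors moved the median over all tested genes only from -0.00227 to -0.00324, so they could hardly have moved the list. The fall thus does not depend on which of these scalings was used, and other scalings were not tested. A lower level per eye cell by genotype was not tested and stays open, as does a change in other cell types.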

How the results depend on the processing

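Fits without ribosomal RNA genes, fits without replicate 1 of every genotype and leave-one-out fits for overlaps were chosen after the data were seen. Of 192 alternative counts of called genes 178 stayed within 1.5 times the reported count, and of 148 alternative overlap counts 143 did. With a fold change of at least 2 the counts were 1520 for scrib, 20 for fos, 304 for CtBP, 1171 for scrib fos and 1898 for CtBP scrib against control. They were 858 for scrib fos and 413 for CtBP scrib against scrib, 1101 for scrib fos against fos, 1759 for CtBP scrib against CtBP, 1460 between the double mutants, and 677 and 303 for the interactions with fos and CtBP, fewer by construction. Leaving out 1 library gave 5142 to 5719 for scrib, 57 to 96 for fos, 1185 to 1351 for CtBP, 4443 to 5112 for scrib fos and 5871 to 6097 for CtBP scrib against control. It gave 3535 to 3931 for scrib fos and 1627 to 1846 for CtBP scrib against scrib, 4476 to 5155 for scrib fos against fos, 5470 to 5825 for CtBP scrib against CtBP, 4744 to 5098 between the double mutants, and 2106 to 2519 and 939 to 1118 for the interactions. The fos count was 71 without fos replicate 1 and 57 without fos replicate 2, and the cause was not tested. Overlaps ranged from 31 to 55 for fos with CtBP against control, 43 to 91 for the fos effect with and without scrib, 261 to 313 for fos with CtBP in scrib tissue. They were 3090 to 3549 and 4202 to 4562 for the scrib effect with and without fos and CtBP, 495 to 599 for the CtBP effect with and without scrib, and 2256 to 2714 and 314 to 403 for scrib changes that went back in scrib fos and CtBP scrib.

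Of 1537 alternatives of called gene lists 1492 kept the call and 45 lost it, and of 3323 of uncalled lists 3208 stayed uncalled and the others gained a call. For named genes 2296 of 2383 alternatives kept the call and 87 lost it, and 256 of 268 stayed uncalled and 12 gained a call. None reversed. For the kay transcript, the interaction of scrib with fos (-0.55, adjusted p = 0.0479) was not called with DESeq2 size factors (0.0578), with no filter (0.116), with only the compared groups (0.132) or without ribosomal RNA genes (0.0586). Nor was it without control replicate 3, fos replicate 2 or 3, scrib fos replicate 2 or 3 or scrib replicate 1, 2 or 3 (0.0627 to 0.104). With no filter 28 uncalled lists were called and 1 lost its call, with a filter of 5 CPM 9 were called and 6 lost it, and with only the compared groups 10 were called and 3 lost it. Immune effectors were called with a filter of 5 CPM in scrib against control (0.0174) and scrib fos against scrib (0.00279). The Hippo target list was called with no filter in CtBP against control (0.0386) and in CtBP scrib against control (0.0312). Without replicate 1 of every genotype the fos count was 79 and the CtBP count 1176, 18 uncalled lists were called and 3 lost their call, and the share of higher genes among fos calls went from 25.9% to 39.2%. The losses were photoreceptor genes in CtBP against control (0.129), glycolytic genes in CtBP scrib against control (0.0567) and cell cycle genes in scrib fos against scrib (0.0685). The gains included Hippo targets in CtBP (0.00708) and CtBP scrib (0.0278) against control, and cell cycle (0.00119), ecdysone and fat body genes (0.00107 each) in fos against control. The salivary gland list had no measured member, and so no value, under the filter of 5 CPM in 3 libraries. The replicate block gave 5782 calls for scrib and 112 for fos and 1564 for CtBP against control, 4071 for scrib fos and 2049 for CtBP scrib against scrib, and 2483 and 1133 for the interactions. Same-numbered libraries of different genotypes correlated with a median of 0.0523 in their deviations. With the block Mlc2 (0.0536), Act57B (0.0746) and ImpL1 (0.0748) were not called. Nor were the photoreceptor list in CtBP against control (0.0730), glycolytic genes in CtBP scrib against control (0.0688), cell cycle and ecdysone genes in scrib fos against scrib (0.0737 each), polarity, antennal and ecdysone genes (0.0852 each) and EGFR genes (0.0517) between the double mutants and sex markers in the CtBP interaction (0.0538). Blood cell (0.0448) and stress genes (0.0340) in CtBP scrib against scrib and Hippo targets in CtBP scrib against control (0.0318) were called with it, and it changed no other call of a reported list or named gene. Depth limits genes near the floor of 3 counts per group.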

Other observations

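The genes in this part were picked after their values were seen, so they stand for themselves and not for their lists, and no test was added for them.

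Single ecdysone response genes were lower in scrib than in control and higher in scrib fos than in scrib, among them ImpE2 and ImpE3. As a list, ecdysone genes were not called in scrib against control (adjusted p = 0.0633). In scrib fos against scrib they were called (0.0260), with an adjusted p = 0.669 with an estimated correlation. That call ended with a filter of 5 CPM (0.0545) and without scrib replicate 3 (0.1001). ImpE2 stood at 2390 ± 555 CPM in control, 279 ± 34.2 in scrib (-3.099, adjusted p = 9.24e-08) and 1013 ± 95.4 in scrib fos (1.86 against scrib, adjusted p = 1.68e-05), and ImpE3 at 137.5 ± 33.6, 39.3 ± 3.36 and 149 ± 11.9. The receptor gene EcR was not called in scrib (0.14, adjusted p = 0.193) and was lower in scrib fos than in scrib (-0.47, adjusted p = 3.73e-04).

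Single genes of other lists were higher in scrib than in control and lower in scrib fos than in scrib. The polarity gene l(2)gl was at 356 ± 13.6 CPM in control, 509 ± 14.2 in scrib and 354 ± 41.8 in scrib fos. The caspase gene Drice was higher in scrib (0.51, adjusted p = 8.40e-09) and lower in scrib fos (-0.41, adjusted p = 3.69e-07). FASN1, which encodes a fatty acid synthase and stands in the fat body list, went from 153 ± 3.85 to 1099 ± 122.8 and to 348 ± 16.5 CPM. Neither the polarity nor the cell death list was called in scrib against control (adjusted p = 0.265 each) or in scrib fos against scrib (0.154 and 0.328).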
